A study of Mus musculus with 30 samples.

How the data were processed

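The analysis started from the read count tables deposited by the authors, one for ileum and one for lung, each with 24062 gene symbols, of which 21769 in the ileum and 20842 in the lung had a count. Upstream steps were not repeated here: per the submitters' processing notes, bases were called with CASAVA and reads aligned to mm10 with TopHat2, without versions. The tool, annotation and filters that turned alignments into counts are not given in the sources used here, nor is the strand of the libraries. Per the labels' protocols, the post-caval lung lobe or a small piece of terminal ileum went into RNAlater, RNA was purified with a Purelink kit, poly-A RNA was selected, and libraries were made with the Nugen Ovation ultralow kit. Of the ileum symbols, 27 had been turned into dates, and 24035 symbols were shared by the tables. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples. The sex given by the labels matched the expression of sex-linked genes in 30 of 30 libraries, and no pair of libraries of the same genotype and tissue was as alike as resampling of the same library would be. Pairs across genotypes were not compared. Reads of close paralogs (Defa, Retn, Gsdmc, Reg3, Cyp3a and Mcpt genes) may be shared between them, which the counts do not resolve.

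Groups, comparisons, gene lists and alternatives were fixed before the data were examined. Counts were filtered with filterByExpr and normalized with trimmed mean of M-values (TMM), and genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) with Benjamini-Hochberg adjustment within each comparison, at an adjusted p under 0.05. The ileum model held genotype and sex, and the lung model also held sequencing batch, with 12 and 9 residual degrees of freedom. The tests covered 14959 ileum and 15885 lung genes, and the biological coefficient of variation was 0.308 in the ileum and 0.130 in the lung. The tissue difference came from a joint model with sex within tissue and lung batch, over 16867 genes. The 10 most abundant genes held 5.96 to 11.0% of the counts of an ileum library and 6.78 to 9.08% of a lung library.

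The genes named for each comparison followed a rule fixed before testing. Tnfsf15 and Tnfrsf25 were always named, then the 8 largest and 8 smallest fold changes with an adjusted p under 0.05 and a mean log2 CPM of at least 1, passing over immunoglobulin and T cell receptor segments and unnamed gene models. Then came up to 4 called members per list by smallest adjusted p. For the tissue difference 5 genes per direction were taken, and any gene given for a comparison outside this rule was chosen after its values were seen. The results of 2 genes that the rule named are not reported here. The 32 lists held 415 symbols, of which 410 were matched, 6 of them by synonym, and 5 were not. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with the correlation estimated from the data. Lists of tissue-foreign cells, blood and stress genes were included to check for admixture and RNA handling. Lists overlap, so they are not independent. Retnlb, Clca3 and Fcgbp belong to the IL-4 and IL-13 list and to the goblet cell list. Hpgds belongs to the type 2 lymphocyte and tuft cell lists, and Icos to the type 2 lymphocyte and T cell activation lists. The IL-4 and IL-13 list also shares Ccl22 with the dendritic cell list and Itln1 with the Paneth cell list. A count adjusted over the list alone applies the Benjamini-Hochberg method to the tested members of that list. Over all tested genes the share called against WT was 8.06% in Mem and 28.7% in Mem+Sol ileum, and 9.46% and 0.844% in the lung. Between the transgenic genotypes it was 0.0134% in the ileum and 2.23% in the lung. Counts of called members are to be read beside these shares. Positions are those of GRCm38 patch 6. Ratios against a group with 1 to 3 counts carry an exact 95% interval, and 0 counts were taken to allow up to 3, and these intervals and floors cover counting error only.

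Alternatives were DESeq2 1.42.0, relative log expression normalization, no filter beyond 1 count, no sex term, only the 2 genotypes compared, the replicate number as a block, and each library left out, and in the lung also no batch term and each batch alone. Thinning the ileum libraries to the smallest total, all alternatives of the shared counts, and the values of single genes within each batch were added after the data were seen. Batch 1 alone was fitted with a sex term and batch 2 alone without one, so the 2 batch values of a gene come from unlike models. Their standard errors are not printed below and were large for some genes, such as 1.95 for Fbp1 in batch 2 (Mem against WT). Replicate numbers were not taken as pairs. The correlation of residuals between libraries of the same number ran from -0.350 to 0.552 in the ileum (8 of 15 above 0.1) and from -0.317 to 0.354 in the lung (5 of 13). Its median was 0.204 in the ileum, against -0.0197 for other pairs across genotypes, and 0.0393 against -0.0036 in the lung. In the ileum 8 of 16 libraries correlated best with a library of their own number, so a pairing there was not excluded. With the replicate number as a block, ileum Mem and Mem+Sol against WT gave 1688 and 3285 calls. In simulated counts with known changes the same code recovered 40.4 to 45.5% of log2 changes of 1 and 86.9 to 91.9% of changes of 2 in the ileum, and 78.6 to 86.0% and 98.0 to 99.0% in the lung, with 2.90 to 8.59% of the calls false. For the tissue difference it recovered 31.0 to 34.0% and 72.5 to 76.5%, with 3.64 to 7.08% false. Every per-sample column of the tables was used.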

Results

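Gene expression was measured by RNA sequencing in the lung and the terminal ileum of C57BL/6 mice of 3 genotypes. Mem mice overexpressed TL1A in a membrane-restricted form, and Mem+Sol mice overexpressed the membrane-bound and the soluble form. TL1A, encoded by Tnfsf15, is a cytokine of the tumour necrosis factor family, and its receptor DR3, encoded by Tnfrsf25, is carried by T cells and innate lymphoid cells. The remaining group is labelled WT and served as the control, although the wording of its label also mentions TL1A under the CD2 promoter, which drives expression in lymphocytes. The ileum series held 5 WT, 5 Mem and 6 Mem+Sol libraries, and the lung series held 5 WT, 5 Mem and 4 Mem+Sol libraries. Mean total counts per library, given as M (mega) counts, were 9.23 in ileum WT, 21.0 in ileum Mem and 21.6 in ileum Mem+Sol. In the lung the group means lay between 29.0 in Mem and 31.7 in Mem+Sol. The libraries allowed 3 comparisons in each tissue, of each transgenic genotype with WT and of the transgenic genotypes with each other, and a comparison of the genotype effects between the tissues. Log2 fold changes are given with their standard error (SE), levels as mean ± SD in CPM (counts scaled to the normalized library size).

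Tnfsf15 transcript rose with both transgenes in the lung and passed no test in the ileum. In the lung it stood at 7.68 ± 2.07 CPM in WT (SD, n = 5), 22.4 ± 1.85 in Mem (n = 5) and 77.3 ± 15.6 in Mem+Sol (n = 4), without overlap between the groups. These levels gave log2 fold changes of 1.57 ± 0.18 for Mem (adjusted p = 0.00024) and 3.37 ± 0.20 for Mem+Sol (adjusted p = 9.9e-07) against WT, and of 1.79 ± 0.18 between Mem+Sol and Mem (adjusted p = 0.00053). Within sequencing batch 1, fitted with sex, the same log2 values were 1.8, 3.90 and 2.09. Within batch 2, fitted without sex, they were 1.45, 2.95 and 1.5, as for all batch values below. In the ileum Tnfsf15 stood at 5.0 ± 2.00 CPM in WT (n = 5), 4.72 ± 0.74 in Mem (n = 5) and 7.23 ± 2.38 in Mem+Sol (n = 6). This gave log2 values of -0.14 ± 0.32 (adjusted p = 0.832) and 0.43 ± 0.33 (adjusted p = 0.336) against WT and 0.57 ± 0.29 (adjusted p = 0.452) between the transgenic genotypes. The sign for ileum Mem against WT turned without WT replicate 2 (log2 0.0074), and that for Mem+Sol against WT turned without WT replicate 1 (log2 -0.028). The effect on Tnfsf15 was larger in the lung than in the ileum for Mem (difference 1.69 ± 0.38, adjusted p = 0.0069) and for Mem+Sol (2.92 ± 0.39, adjusted p = 5.8e-05). Tnfrsf25 rose in Mem lungs, from 5.07 ± 0.46 to 7.99 ± 0.88 CPM (log2 0.63 ± 0.10, adjusted p = 0.0020, 0.72 and 0.49 in the batches). It was lower in Mem+Sol than in Mem lungs (log2 -0.66 ± 0.11, adjusted p = 0.015, -0.74 and -0.60 in the batches), a call that was lost without Mem+Sol replicate 3 (adjusted p = 0.0518). In the ileum Tnfrsf25 gave 0.64 ± 0.32 for Mem (adjusted p = 0.235) and 0.48 ± 0.32 for Mem+Sol (adjusted p = 0.261), and in Mem+Sol lungs it gave -0.03 ± 0.11 (adjusted p = 0.916).

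**Figure D1:**
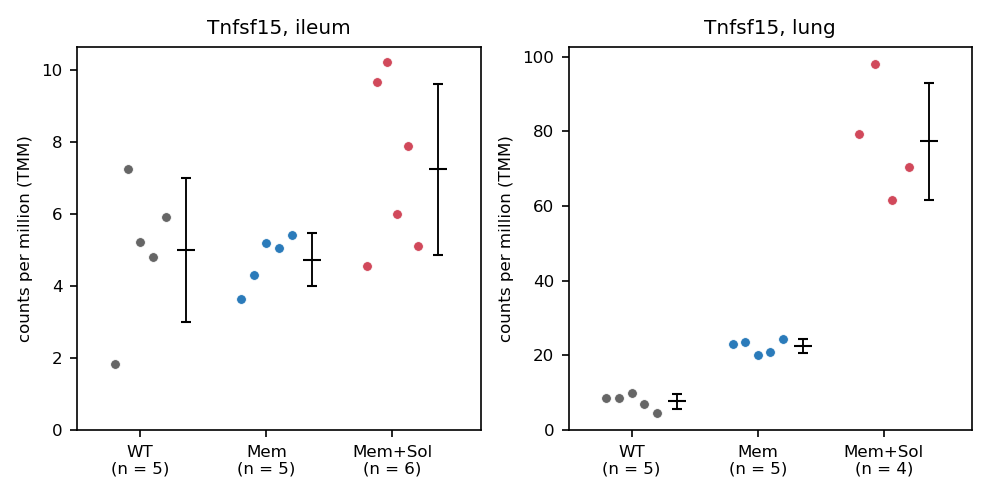
Tnfsf15 in CPM in each library of the ileum and the lung by genotype, with points for libraries and bars for the mean ± SD. In the lung the Mem libraries lie between 20.2 and 24.5 and the Mem+Sol libraries between 61.5 and 97.9, above WT at 4.49 to 9.92, while the ileum groups overlap.

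Most tuft cell genes rose in the ileum of Mem mice. Of 13 tested members 11 rose and none fell, 12 rose when adjusted over the list alone, and the median log2 fold change was 2.59 (camera adjusted p = 3.4e-12, adjusted p = 0.183 with an estimated correlation). Pou2f3, the transcription factor that specifies tuft cells, went from 3.88 ± 0.74 CPM in WT to 24.8 ± 8.84 in Mem (log2 2.63 ± 0.27, adjusted p = 5.4e-05). Gfi1b, another tuft cell transcription factor (3.31 ± 0.38), Trpm5, the cation channel of taste transduction (2.72 ± 0.33), and Alox5, which starts leukotriene synthesis (3.21 ± 0.40), rose as well. Genes of type 2 lymphocytes rose in 7 of 11 tested members, 9 when adjusted over the list alone, and none fell (camera adjusted p = 6.8e-06, adjusted p = 0.183 with an estimated correlation). They included Il1rl1, the IL-33 receptor, which went from 7.53 ± 1.56 to 161 ± 81.1 CPM (log2 4.42 ± 0.56, adjusted p = 0.00035), and Il17rb, the IL-25 receptor (2.35 ± 0.41). Genes that respond to IL-4 and IL-13 rose in 7 of 16 members and fell in 1, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.0010, adjusted p = 0.313 with an estimated correlation). Among them were Retnlb, a goblet cell protein induced in worm infection, which went from 7.09 ± 10.9 to 253 ± 166 CPM (log2 5.46 ± 0.84, adjusted p = 0.0013). Others were Retnla (4.17 ± 0.73), the eosinophil chemokine Ccl24 (5.14 ± 0.94) and the goblet cell product Clca3, now named Clca1 (1.65 ± 0.35).

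Some structural, vascular and granulocyte genes were also higher in Mem ileum. Extracellular matrix genes rose in 7 of 15 members (10 adjusted over the list alone, camera adjusted p = 6.2e-08, adjusted p = 0.183 with an estimated correlation). Fibronectin, Fn1, was at 152 ± 41.9 CPM in WT and 899 ± 376 in Mem (log2 2.51 ± 0.39, adjusted p = 0.0014) and Sparc, Col1a2 and Tnc gave log2 values between 1.34 and 1.76. Smooth muscle genes rose in 5 of 10 members (10 adjusted over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.245 with an estimated correlation), among them the enteric actin Actg2 (2.57 ± 0.53) and desmin, Des (1.83 ± 0.40). Endothelial genes rose in 6 of 12 members (9 adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.183 with an estimated correlation), including von Willebrand factor, Vwf (1.31 ± 0.29). Of 4 tested eosinophil genes 2 rose (4 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.183 with an estimated correlation), among them Siglec5, now Siglecf, at log2 2.52 ± 0.34. Of 5 neutrophil genes 2 rose (4 adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.313 with an estimated correlation). Retnlg was at 3.11 ± 0.44. The mast cell and progenitor receptor Kit (1.40 ± 0.19, adjusted p = 0.00048) was the 1 called gene of the 9 mast cell genes, 2 adjusted over the list alone (camera adjusted p = 0.0751). The 1 tested gene of exocrine pancreas, the lipase-related Pnliprp1, rose too (5.13 ± 0.69, adjusted p = 0.00043). That list was included to check for admixture. Whether the ileum pieces differed between the groups in their content of muscle, wall or other tissue was not tested.

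Some enterocyte genes and all tested cytotoxic genes were lower in Mem ileum. All 4 tested cytotoxic genes fell, over all genes and adjusted over the list alone (camera adjusted p = 2.0e-05, adjusted p = 0.183 with an estimated correlation). The receptor Klrd1 was at -2.06 ± 0.36 (adjusted p = 0.0035). Granzyme A, Gzma, was at 56.5 ± 40.3 CPM in WT and 9.55 ± 5.22 in Mem (-2.49 ± 0.62, adjusted p = 0.023). The Gzma call was lost without WT replicate 1 or 3 or any of Mem replicates 2 to 5 (adjusted p 0.0572 to 0.0639). Among T cell genes the coreceptor Cd8a (-2.32 ± 0.43, adjusted p = 0.0051) was the 1 that fell, of 14 tested and adjusted over the list alone (camera adjusted p = 0.00020, adjusted p = 0.313 with an estimated correlation). Of 16 genes of type 1 responses 1 fell, 5 adjusted over the list alone (camera adjusted p = 0.00062, adjusted p = 0.313 with an estimated correlation). Enterocyte genes fell in 3 of 18 members and rose in 1, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.00066, adjusted p = 0.270 with an estimated correlation). The drug-metabolising enzyme Cyp3a11 went from 28.7 ± 30.5 to 0.819 ± 1.47 CPM (-4.86 ± 1.05, adjusted p = 0.011), while the fatty acid binding protein Fabp1 was the member that rose (2.77 ± 0.59). Of 11 enteroendocrine genes 4 fell, 6 adjusted over the list alone (camera adjusted p = 0.00083, adjusted p = 0.183 with an estimated correlation). Cell cycle genes had no called member, over all genes or adjusted over the list alone, and a median of -0.31 (camera adjusted p = 0.0187, adjusted p = 0.572 with an estimated correlation). Adipose genes likewise had none with a median of 0.99 (camera adjusted p = 0.0379, adjusted p = 0.572 with an estimated correlation).

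Among the largest increases in Mem ileum over WT were Ppef1 (7.96 ± 1.73), the phospholipase Pla2g4c (6.57 ± 0.46), and the gasdermin pseudogene Gsdmcl-ps (6.13 ± 0.83). Others were the pentraxin Mptx1 (6.09 ± 0.55), the eosinophil ribonuclease Rnase2a (5.76 ± 1.31), the decoy receptor Il13ra2 (5.74 ± 1.16) and Fcrlb (5.65 ± 1.16). WT libraries together held 2 counts of Ppef1, 3 of Rnase2a and 2 of Il13ra2, which gave ratios of 311 (95% counting interval 86.1 to 2574), 77.0 (26.2 to 375) and 77.1 (21.2 to 639). The largest decreases were in Plb1, a brush border phospholipase (-8.54 ± 2.18), lactase, Lct (-7.14 ± 1.91), Cyp3a11, Cyp3a25 (-4.79 ± 0.99), the transporters Slc5a12 (-4.50 ± 1.15) and Slc5a4b (-4.21 ± 0.93), Cyp2c55 (-3.81 ± 1.01) and the antimicrobial lectin Reg3a (-3.58 ± 0.64). Plb1 and Lct rested on WT replicate 2, the smallest ileum library, with 1343 and 518 CPM, and without it their adjusted p was 0.182 and 0.170. Plb1, Lct, Slc5a12, Slc5a4b and Cyp2c55 were not called without Mem replicate 2 (adjusted p 0.0559 to 0.109) or Mem replicate 4 (0.0533 to 0.102). Slc5a12 was also lost without WT replicate 1 (0.0933), Slc5a12 and Cyp2c55 without Mem replicate 3 (0.0663 and 0.0681), Lct, Slc5a12 and Cyp2c55 without Mem replicate 5 (0.0564 to 0.0663), and Cyp2c55 without WT replicate 2, 4 or 5 (0.0501 to 0.0604). Of the other lists, members rose and fell in goblet cells (5 and 4 of 14, 6 and 4 adjusted over the list alone), Paneth cells (2 and 0 of 13, both also over the list alone) and antimicrobial genes (3 and 1 of 13, 3 and 3 over the list alone). They also did in T cell activation (1 and 0 of 13, 1 over the list alone), type 3 lymphocytes (1 and 1 of 4, the same over the list alone) and plasma cells (0 and 1 of 10, 1 and 1 over the list alone). The same held for macrophages (1 and 1 of 12, 1 and 2 over the list alone), dendritic cells (2 and 0 of 12, 3 over the list alone) and alveolar genes (1 and 1 of 10, 2 and 1 over the list alone), and for cardiac and skeletal muscle (1 and 0 of 6, 2 over the list alone) and stress genes (0 and 2 of 12, 2 over the list alone). Stem cell, B cell, airway and red blood cell genes had no called member, with 1 airway gene higher over the list alone. For dendritic cells the median was -0.01, the mean 0.15 and the camera direction upwards, and for type 3 lymphocytes the median was 0.01, the mean -0.08 and the direction downwards. None of these lists passed camera (adjusted p 0.0598 to 0.721), and those of red blood cells and exocrine pancreas, with 1 tested gene each, had no test.

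In total 748 genes rose and 457 fell in Mem ileum, of 14959 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mem replicate 1 stood apart from the other Mem libraries on the first principal component (-24.7 against 17.9 to 26.5, with WT at -59.1 to -38.6), and without it 2396 genes were called. The count was 1926 with DESeq2, 633 with every library thinned to the smallest total (chosen after the data were seen), 448 without Mem replicate 2, 448 without Mem replicate 4, 749 without WT replicate 2, 794 without WT replicate 3, 712 without WT replicate 4, 797 without Mem replicate 3 and 727 without Mem replicate 5.

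**Figure D2:**
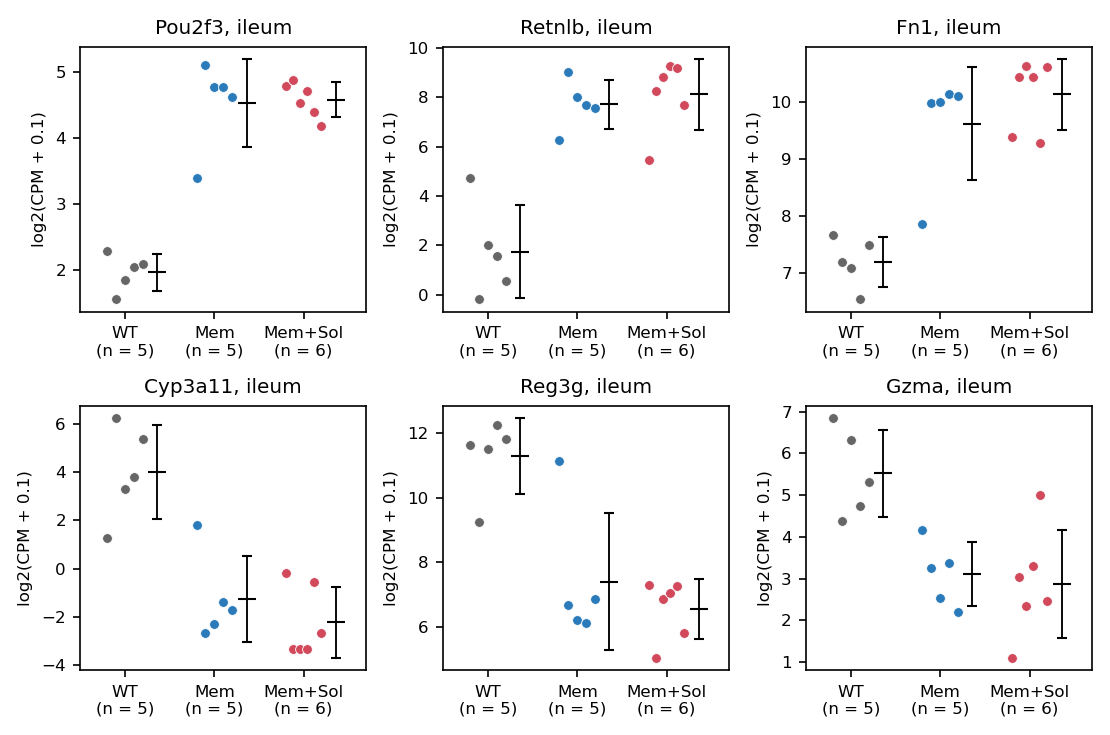
Ileum levels of Pou2f3, Retnlb, Fn1, Cyp3a11, Reg3g and Gzma as log2(CPM + 0.1) in each library by genotype, with points for libraries and bars for the mean ± SD. Pou2f3, Retnlb and Fn1 lie higher in both transgenic genotypes than in WT, and Cyp3a11, Reg3g and Gzma lie lower, with Mem replicate 1 near WT for Reg3g, which was called in Mem+Sol but not in Mem (adjusted p = 0.0749, looked up after the data were seen).

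In the ileum of Mem+Sol mice the same lists of tuft, type 2, matrix and muscle genes rose, and mast cell genes rose with them. Tuft cell genes rose in 12 of 13 members, also adjusted over the list alone (camera adjusted p = 4.2e-08, adjusted p = 0.225 with an estimated correlation). Pou2f3 was at 24.2 ± 4.26 CPM (n = 6, log2 2.58 ± 0.27, adjusted p = 3.9e-05). Type 2 lymphocyte genes rose in 7 of 11 (7 adjusted over the list alone, camera adjusted p = 0.00096, adjusted p = 0.30 with an estimated correlation). Il1rl1 was at 152 ± 92.6 CPM (4.33 ± 0.55). IL-4 and IL-13 responsive genes rose in 10 of 16 and fell in 1, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.00096, adjusted p = 0.307 with an estimated correlation). Retnlb reached 370 ± 225 CPM (5.75 ± 0.84, adjusted p = 0.00026), Retnla 5.75 ± 0.75 and Ccl24 5.97 ± 0.95 on the log2 scale, while the mucus protein Fcgbp fell (-1.62 ± 0.25). Mast cell genes rose in 6 of 9 (8 adjusted over the list alone, camera adjusted p = 8.8e-05, adjusted p = 0.225 with an estimated correlation), among them the proteases Mcpt4 (6.01 ± 0.94), Tpsb2 (4.33 ± 0.69) and Cma1 (4.63 ± 1.02). Eosinophil genes rose in 3 of 4 (4 adjusted over the list alone, camera adjusted p = 0.0034, adjusted p = 0.225 with an estimated correlation). Ccr3 was at 4.11 ± 0.77. Neutrophil genes rose in 3 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0073, adjusted p = 0.307 with an estimated correlation). Retnlg was at 3.86 ± 0.45. Extracellular matrix genes rose in 13 of 15 (14 adjusted over the list alone, camera adjusted p = 2.7e-07, adjusted p = 0.225 with an estimated correlation). Fn1 was at 1197 ± 435 CPM (2.92 ± 0.39). Smooth muscle genes rose in 10 of 10, also over the list alone (camera adjusted p = 4.2e-08, adjusted p = 0.225 with an estimated correlation). Actg2 was at 3917 ± 3671 CPM (3.79 ± 0.54) and Des at 3.01 ± 0.41. Endothelial genes rose in 9 of 12, also over the list alone (camera adjusted p = 8.4e-05, adjusted p = 0.260 with an estimated correlation). Cardiac and skeletal muscle genes rose in 4 of 6, also over the list alone (camera adjusted p = 0.0185, adjusted p = 0.270 with an estimated correlation). This list was included to check for admixture, so its rise may mark tissue content rather than an effect of the genotype. Whether the matrix, muscle and endothelial rises reflect unlike tissue pieces was not tested.

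Most enterocyte genes and all tested cytotoxic genes were lower in Mem+Sol ileum than in WT. Enterocyte genes fell in 11 of 18 members and rose in 1, the same adjusted over the list alone, with a median of -1.44 (camera adjusted p = 8.4e-05, adjusted p = 0.225 with an estimated correlation). Over 10 general epithelial markers chosen after the data were seen the median was -0.27, with Cldn7 (-0.89 ± 0.23) and Cldn3 (-0.85 ± 0.22) lower and Krt18 (1.33 ± 0.24) higher and the other 7 not called. Alkaline phosphatase, Alpi (-1.83 ± 0.30), and the protease Mep1a (-2.03 ± 0.38) fell, whereas Fabp1 rose (3.32 ± 0.60). Of 13 antimicrobial genes 3 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.649). Reg4 was at 4.79 ± 0.59 and the bactericidal lectin Reg3g at 3066 ± 1570 CPM in WT and 108 ± 52.1 in Mem+Sol (-4.58 ± 0.92, adjusted p = 0.0020). Enteroendocrine genes fell in 4 of 11 and rose in 1, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0111, adjusted p = 0.270 with an estimated correlation), with Chga, a granule protein, at -1.40 and somatostatin, Sst, at 1.45 ± 0.30. Cytotoxic genes fell in 4 of 4, also over the list alone (camera adjusted p = 0.00096, adjusted p = 0.225 with an estimated correlation). Klrd1 was at -2.49 ± 0.35. T cell genes fell in 2 of 14 (1 adjusted over the list alone, camera adjusted p = 0.0160, adjusted p = 0.523 with an estimated correlation). Cd8a was at -3.13 ± 0.42. Type 1 response genes fell in 5 of 16 (7 adjusted over the list alone, camera adjusted p = 0.0073, adjusted p = 0.382 with an estimated correlation). Cell cycle genes fell in 3 of 15 (0 adjusted over the list alone, camera adjusted p = 0.00067, adjusted p = 0.382 with an estimated correlation). Of all 14959 tested genes 1810 fell, so 2 of 14 T cell and 3 of 15 cell cycle genes say little on their own. The remaining 13 lists with a test did not pass camera (adjusted p 0.0536 to 0.871). For antimicrobial genes the median was 0.16 against a mean of -0.64, and for stress genes the median was -0.11 against a mean of 0.33.

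Among the largest increases in Mem+Sol ileum over WT were Ppef1 (9.36 ± 1.69), fast skeletal troponin, Tnnt3 (8.58 ± 0.96), and the caseins Csn2 (7.67 ± 0.64) and Csn3 (7.39 ± 0.73). Others were the chitinase-like protein Chil4 (7.31 ± 1.54), Rnase2a (6.97 ± 1.27) and Mptx1 (6.59 ± 0.56). Against the few WT counts the ratios were 908 for Ppef1 (counting interval 251 to 7501), 362 for Csn2 (100 to 2988), 260 for Csn3 (88.9 to 1263) and 165 for Rnase2a (56.4 to 802). The largest decreases were in Plb1 (-7.62 ± 2.26), Cyp3a11 (-6.38 ± 1.16), Lct (-6.06 ± 1.73), Slc5a12 (-5.43 ± 1.14), the sphingomyelinase Enpp7 (-5.43 ± 1.46), Akr1b7 (-5.41 ± 0.86), Cyp3a25 (-5.40 ± 0.96) and Aadac (-5.18 ± 1.06). Without WT replicate 2 Plb1, Lct and Enpp7 were not called (adjusted p = 0.261, 0.657 and 0.0558), and Plb1 was also lost without Mem+Sol replicate 4 (0.0613) or 6 (0.0733). In total 2486 genes rose and 1810 fell, and with every ileum library thinned to the smallest total, an alternative chosen after the data were seen, 2596 were called. Mem+Sol replicate 1 stood apart from the other Mem+Sol libraries on the first principal component (-2.23 against 25.8 to 45.1), and without it 4793 were called.

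Of the genes called in the ileum, 1155 were called in Mem and in Mem+Sol in the same direction, 718 higher and 437 lower, and none in opposite directions. These were 95.9% of the Mem calls and 26.9% of the Mem+Sol calls, where independent lists would share 124 higher and 55.3 lower genes. In 20 simulations in which the genotypes did not differ, with genes drawn independently, the median shared count was 0. Unchanged groups yield almost no calls, so that count was near 0 by design. It does not measure sharing that comes from the common WT libraries. The correlation of the fold changes across genes, which are not independent replicates, was 0.90 against 0.56 simulated, and the covariance was 0.60 against 0.06. With the WT libraries split between the comparisons, 67 to 425 genes were shared over 20 splits. Each comparison then had only part of the WT libraries and less power, so these counts are not on a par with 1155. The correlation over the splits had a median of 0.73 (0.55 to 0.79). The shared count was 2156 without Mem replicate 1, 444 without Mem replicate 2, and 441 without Mem replicate 4. It was 719 without WT replicate 2, 759 without WT replicate 3, 690 without WT replicate 4, 759 without Mem replicate 3 and 695 without Mem replicate 5.

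Between Mem+Sol and Mem ileum 2 genes differed, the milk proteins Csn2 (9.18 ± 0.61, adjusted p = 5.5e-07) and Csn3 (7.96 ± 0.66, adjusted p = 7.9e-06). Csn2 stood at 15.1 ± 9.02 CPM in Mem+Sol (n = 6), and Mem libraries together held 2 counts, a ratio of 898 (counting interval 248 to 7421). At an unadjusted p under 0.05 there were 1744 genes, and DESeq2 called 40 after adjustment. Leaving out Mem+Sol replicate 1 gave 8 calls, with Csn2 and Csn3 called under each left-out library. No member of any list was called over all genes. Mast cell genes had 5 of 9 members higher when adjusted over the list alone and a median of 2.15 (camera adjusted p = 2.5e-07, adjusted p = 0.206 with an estimated correlation). Mcpt4, chosen here after its values were seen, was at 0.50 CPM in Mem and 8.50 ± 6.39 in Mem+Sol. Smooth muscle genes had 5 of 10 (median 0.97, camera adjusted p = 8.9e-05, adjusted p = 0.474 with an estimated correlation). Stress, matrix and dendritic cell genes passed camera upwards, with 0, 0 and 1 member adjusted over the list alone (adjusted p = 0.0044, 0.0201 and 0.0262, and adjusted p = 0.474, 0.661 and 0.532 with an estimated correlation). Goblet, enterocyte, stem cell and cell cycle genes passed downwards with no member adjusted over the list alone (adjusted p = 0.0057, 0.0057, 0.0035 and 0.0051, and adjusted p = 0.474, 0.474, 0.474 and 0.661 with an estimated correlation). The other 21 lists did not pass (adjusted p 0.0554 to 0.975).

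In Mem lungs, genes that respond to IL-4 and IL-13 showed the largest rise of the lists tested there. Of 16 tested members 13 rose and none fell, also adjusted over the list alone, with a median log2 fold change of 2.87 (camera adjusted p = 1.2e-16, adjusted p = 0.0683 with an estimated correlation). Clca3, a mucous cell product, went from 2.49 ± 1.76 CPM in WT to 856 ± 533 in Mem (log2 8.14 ± 0.71, adjusted p = 0.00012, 7.61 and 9.24 in batches 1 and 2). Retnla, a marker of alternatively activated macrophages, went from 47.9 ± 12.5 to 1334 ± 1010 CPM (log2 4.3 ± 0.45, 4.48 and 3.90 in the batches), and the chemokine Ccl8 rose by 3.89 ± 0.33 (4.55 and 3.13). Goblet cell and mucus genes rose in 6 of 12 members (8 adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.101 with an estimated correlation), including the airway mucin Muc5ac (2.93 ± 0.35, 2.76 and 3.41). Epithelial antimicrobial genes rose in 5 of 7 (6 adjusted over the list alone), the 1 list whose camera result (adjusted p = 5.1e-07) held with an estimated correlation (adjusted p = 0.0401). They were led by Lcn2 (2.19 ± 0.19, 2.44 and 1.85), which binds bacterial siderophores, and the acute phase protein Saa3 (3.19 ± 0.30, 3.29 and 2.90). All 15 cell cycle genes rose, also over the list alone (median 1.19, camera adjusted p = 3.0e-16, adjusted p = 0.0994 with an estimated correlation). The kinase Cdk1 was at 3.27 CPM in WT and 10.7 in Mem (1.59 ± 0.24, 2.04 and 1.00).

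Genes of several lymphocyte and myeloid lists rose in Mem lungs too. T cell activation and regulatory T cell genes rose in 12 of 15 members and fell in 1, the same adjusted over the list alone (median 1.45, camera adjusted p = 3.6e-11, adjusted p = 0.0958 with an estimated correlation). Foxp3, the regulatory T cell transcription factor, went from 1.20 ± 0.41 to 10.8 ± 3.52 CPM (3.00 ± 0.25, adjusted p = 6.4e-05, 3.18 and 2.92 in the batches). The costimulatory receptor Tnfrsf4 was at 1.81 ± 0.20 (2.08 and 1.48), and Tnfrsf9 at 2.69 ± 0.30 (3.08 and 2.26). T cell genes rose in 11 of 16 (13 adjusted over the list alone, camera adjusted p = 6.7e-08, adjusted p = 0.152 with an estimated correlation). Cd4 was at 1.18 ± 0.15 (1.28 and 1.18). Type 2 lymphocyte genes rose in 5 of 10, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00011, adjusted p = 0.0994 with an estimated correlation). Among them were Icos (1.54 ± 0.16, 1.75 and 1.3), Klrg1 (1.62 ± 0.18, 1.61 and 1.69), the chemokine receptor Ccr8 (2.62 ± 0.34, 3.18 and 1.83) and Il1rl1 (1.48 ± 0.20, 1.58 and 1.29). Plasma cell genes rose in 4 of 10 (6 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.101 with an estimated correlation). The antibody joining chain Igj, now Jchain, was at 23.4 CPM in WT and 287 in Mem (3.56 ± 0.37, 4.11 and 2.99). Macrophage genes rose in 8 of 13 (10 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.0994 with an estimated correlation). The complement gene C1qc was at 1.16 ± 0.15 (1.31 and 0.96). Dendritic cell genes rose in 9 of 12, also over the list alone (camera adjusted p = 1.2e-08, adjusted p = 0.0734 with an estimated correlation). Cd209a was at 1.43 ± 0.15 (1.76 and 1.02) and the chemokine Ccl22 at 2.26 ± 0.26 (2.7 and 1.61). Type 1 response genes rose in 5 of 16, also over the list alone (camera adjusted p = 0.0042, adjusted p = 0.398 with an estimated correlation). The interferon-induced chemokine Cxcl9 was at 3.02 ± 0.54 (3.76 and 2.30), and Cxcl10 at 2.18 ± 0.29 (2.48 and 2.09). Type 3 lymphocyte genes rose in 3 of 8, with 3 higher and 1 lower over the list alone (camera adjusted p = 0.0313, adjusted p = 0.155 with an estimated correlation). Matrix genes rose in 2 of 16, also over the list alone (camera adjusted p = 0.0163, adjusted p = 0.466 with an estimated correlation). The protease inhibitor Timp1 was at 1.18 ± 0.19 (1.20 and 1.05).

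In Mem lungs 3 endothelial genes and 1 smooth muscle gene fell. Endothelial genes fell in 3 of 12 members (6 adjusted over the list alone, camera adjusted p = 0.00057, adjusted p = 0.159 with an estimated correlation). The angiopoietin receptor Tek was at -0.49 ± 0.08 (-0.59 and -0.29 in the batches). Smooth muscle genes fell in 1 of 10 (4 adjusted over the list alone, camera adjusted p = 0.0065, adjusted p = 0.348 with an estimated correlation), the filament protein Synm (-0.52, -0.59 and -0.34). Of 14 airway genes 1 rose and 3 fell, the same over the list alone (camera adjusted p = 0.0904). The club cell enzyme Cyp2f2 was at -0.62 ± 0.10 (-0.65 and -0.52). Of 15 alveolar genes 2 rose and 1 fell, with 3 and 1 over the list alone (camera adjusted p = 0.128), among them the surfactant protein Sftpd (0.87, 1.08 and 0.55). Members rose and fell also in tuft cells (3 and 0 of 9, 3 over the list alone, camera adjusted p = 0.0555), enterocytes (1 and 1 of 7, 1 and 2 over the list alone) and stem cells (0 and 1 of 8, 2 over the list alone). They did so too in eosinophils (2 and 0 of 6, 3 over the list alone), B cells (1 and 1 of 14, the same over the list alone) and neutrophils (3 and 0 of 13, also over the list alone). For neutrophils the median was -0.42 and the mean 0.02, with a camera direction upwards (adjusted p = 0.612). Mast cell, cytotoxic, cardiac and skeletal muscle, adipose and stress genes had no called member, and no list of these groups passed camera (adjusted p 0.0555 to 0.946). Paneth, enteroendocrine, pancreas and red blood cell genes had 2 tested members each, none called, and no test.

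The largest increases in Mem lungs were in Rnase2a (9.07 ± 1.04, 10.09 and 7.71 in the batches), Chil4 (8.31 ± 1.04, 8.84 and 7.15), Clca3, the gluconeogenic enzyme Fbp1 (4.96 ± 0.91, 5.28 and 4.85) and the macrophage elastase Mmp12 (4.9 ± 0.68, 5.08 and 4.63). Next came Retnla, the chemokine Ccl20 (4.26 ± 0.53, 4.56 and 3.76) and H2-M2 (3.95 ± 0.55, 4.04 and 3.92). The largest decreases were in Bpifa1, a secreted airway protein (-1.68 ± 0.43, -2.08 and -1.25), the sulfotransferase Sult1d1 (-1.40 ± 0.23, -1.48 and -1.25), Asgr1 (-0.96, -0.89 and -1.02), Coro6 (-0.89, -1.18 and -0.45), Cyp2a5 (-0.88, -1.01 and -0.81), Sytl5 (-0.87, -0.99 and -0.71), the paraoxonase Pon1 (-0.86 ± 0.14, -0.93 and -0.71) and Cst8 (-0.85, -0.77 and -0.80). Of these, Bpifa1, Asgr1, Coro6, Cyp2a5, Sytl5 and Cst8 were each lost without WT replicate 5 (adjusted p 0.0561 to 0.146) or Mem replicate 3 (0.0675 to 0.115). Several were lost without another library as well: Bpifa1 without WT replicate 3 or Mem replicate 1 (0.0611 to 0.0656), Sytl5 without WT replicate 2 or Mem replicate 2 (0.0571 to 0.0735) and Coro6 without WT replicate 3 or Mem replicate 2, 4 or 5 (0.0679 to 0.0794). Asgr1 and Cst8 were lost without any of WT replicates 2 to 4 or Mem replicates 1 and 2 (0.0520 to 0.0980), and Asgr1 also without WT replicate 1 (0.0641). In total 1018 genes rose and 485 fell, of 15885 tested. Batch 1 alone called 956, and batch 2 alone, with 2 libraries per genotype, called 5. The total was 627 without WT replicate 5, 658 without Mem replicate 3, 956 without WT replicate 3 and 985 without Mem replicate 2, and 524 with no batch term. It was 2006 without Mem replicate 1, which stood apart on the first principal component (-4.82 against 14.2 to 36.6 in the other Mem lungs). Calls were 67.7% upwards, and over the alternatives this share ran from 56.6% with DESeq2 to 92.7% with no batch term.

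The genes called in Mem+Sol lungs against WT included Clca3, Retnla and Foxp3. Clca3 reached 148 ± 59.4 CPM (n = 4, log2 5.75 ± 0.69, adjusted p = 0.0045, 4.24 and 7.37 in the batches). Retnla reached 310 ± 86.2 (2.45 ± 0.43, adjusted p = 0.023, 1.85 and 2.61) and Foxp3 6.13 ± 2.87 (2.11 ± 0.27, adjusted p = 0.0029, 2.53 and 1.69). Csn2 gave the largest fold, with 206 ± 137 CPM in Mem+Sol and 2 counts over the WT libraries (ratio 15529, counting interval 4298 to 128230, log2 14.14 and 12.68 in the batches). The other large increases were in Tnfsf15, Ccl20 (3.14 ± 0.58, 3.58 and 2.27), Igj (2.84 ± 0.37, 3.71 and 2.08), Ccl8 (2.80 ± 0.34, 3.24 and 2.32) and the inhibitory receptor Ctla4 (2.27 ± 0.35, 3.11 and 1.31). The largest decreases were in the scavenger receptor Cd163l1, carried by gamma-delta T cells (-2.37 ± 0.37, -2.59 and -2.32), the laminin Lama1 (-1.40 ± 0.25, -1.69 and -1.15), Dhrs9 (-1.27, -1.55 and -1.12), Bcl6b (-1.10, -0.38 and -1.46), Dusp8 (-1.03, -0.42 and -1.40), Lzts1 (-1.0, -0.74 and -0.96), the chaperone Dnajb1 (-0.90 ± 0.15, -0.46 and -1.22) and Cd59a (-0.87, -0.45 and -1.32). Of the 29 named genes that were called, 24 were lost without Mem+Sol replicate 4 (adjusted p 0.0738 to 0.347), 19 without WT replicate 2 (0.0590 to 0.185), and 14 without WT replicate 5 (0.0580 to 0.156). The others were 11 without WT replicate 4 (0.0506 to 0.0748), 10 without WT replicate 3 (0.0507 to 0.0757), and 8 without WT replicate 1 (0.0506 to 0.0779). Another 7 were lost without Mem+Sol replicate 3 (0.0550 to 0.0844), 4 without Mem+Sol replicate 1 (0.0523 to 0.0718) and 1 without Mem+Sol replicate 2 (0.0519). Tnfsf15, Csn2, Clca3, Ccl8 and Foxp3 were called under each left-out library.

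By list, IL-4 and IL-13 responsive genes rose in 3 of 16 members in Mem+Sol lungs against WT (10 adjusted over the list alone, median 1.17, camera adjusted p = 4.6e-07, adjusted p = 0.185 with an estimated correlation). T cell activation genes rose in 4 of 15 (8 adjusted over the list alone, camera adjusted p = 8.5e-08, adjusted p = 0.175 with an estimated correlation). Members also rose among T cells (1 of 16, 12 adjusted over the list alone, camera adjusted p = 5.3e-09, adjusted p = 0.179 with an estimated correlation) and plasma cells (1 of 10, 4 over the list alone, camera adjusted p = 0.00018, adjusted p = 0.175 with an estimated correlation). They rose among dendritic cells (2 of 12, 7 over the list alone, camera adjusted p = 2.0e-06, adjusted p = 0.175 with an estimated correlation) and antimicrobial genes (2 of 7, 4 higher and 1 lower over the list alone, camera adjusted p = 0.0044, adjusted p = 0.175 with an estimated correlation), and among type 2 lymphocytes (1 of 10, 4 higher and 1 lower over the list alone, camera adjusted p = 0.0166, adjusted p = 0.257 with an estimated correlation). No macrophage gene was called, with 5 of 13 over the list alone (camera adjusted p = 0.00014, adjusted p = 0.257 with an estimated correlation). Eosinophil, B cell and cytotoxic genes had no called member, with 2, 1 and 0 over the list alone (camera adjusted p = 0.0200, 0.0148 and 0.0166, and adjusted p = 0.175, 0.542 and 0.542 with an estimated correlation). Smooth muscle genes fell in 1 of 10, Smtn at -0.56 ± 0.09 (6 adjusted over the list alone, camera adjusted p = 5.6e-05, adjusted p = 0.214 with an estimated correlation). Smtn was lost without WT replicate 2, WT replicate 5 or Mem+Sol replicate 4 (adjusted p 0.0580 to 0.114). Matrix and endothelial genes had no called member, over all genes or the list alone, and passed downwards (camera adjusted p = 0.0169 and 0.0200, and adjusted p = 0.542 and 0.412 with an estimated correlation). Cell cycle genes had no called member and a median of 0.18 (camera adjusted p = 0.0987), and the other 13 lists did not pass either (adjusted p 0.0654 to 0.977). In total 83 genes rose and 51 fell by edgeR's quasi-likelihood test, and DESeq2 called 323 higher and 311 lower. The count was 10 without Mem+Sol replicate 4, 22 without WT replicate 2, 50 without WT replicate 5 and 500 without Mem+Sol replicate 2 (248 higher and 252 lower). It was 15 in batch 1 alone, 1190 in batch 2 alone (539 higher and 651 lower), 18 with no batch term, 243 with no sex term and 68 with the replicate number as a block. Its size and its balance of directions are loosely fixed by these libraries.

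Of the genes called in the lung, 80 were called in Mem and in Mem+Sol in the same direction, 68 higher and 12 lower, and none in opposite directions, which were 5.32% of the Mem calls and 59.7% of the Mem+Sol calls. Independent lists would share 5.32 higher and 1.56 lower genes. In 20 simulations in which the genotypes did not differ the shared count was at most 1. As in the ileum, that count was near 0 by design and does not measure sharing through the common WT libraries. The correlation across genes was 0.65 against 0.49 simulated, and the covariance 0.09 against 0.02. With the WT libraries split between the comparisons 1 to 28 genes were shared, again with less power than for the 80. The correlation over the splits had a median of 0.47 (0.30 to 0.56). The shared count was 7 without Mem+Sol replicate 4, 15 without WT replicate 2, 22 without WT replicate 5, 44 without Mem replicate 3, 45 without WT replicate 3, 169 without Mem+Sol replicate 2 and 217 without Mem replicate 1.

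**Figure D3:**
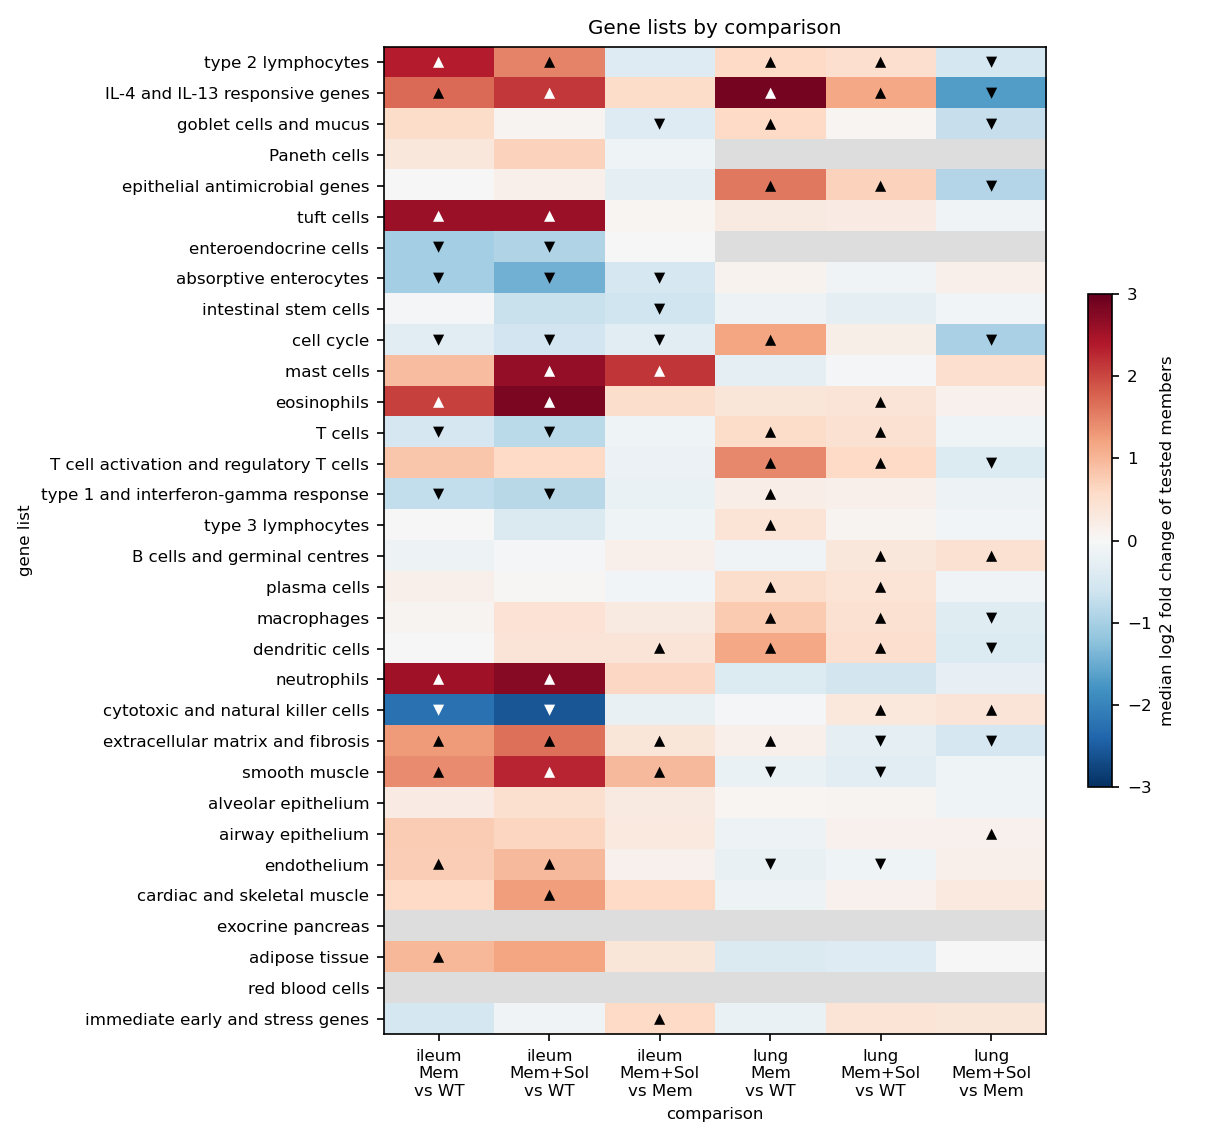
Gene lists by comparison, with colour for the median log2 fold change of the tested members (limited at 3), triangles for lists with a camera adjusted p under 0.05 in the direction they point, and grey for lists with fewer than 3 tested members. Tuft cell genes have medians of 2.59 and 2.58 in the ileum comparisons with WT, and IL-4 and IL-13 responsive genes one of 2.87 in Mem lungs.

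Compared with Mem lungs, Mem+Sol lungs had lower levels of IL-4 and IL-13 responsive genes and of cell cycle genes, although their Tnfsf15 level was higher. IL-4 and IL-13 responsive genes fell in 7 of 16 members (13 adjusted over the list alone, median -1.68, camera adjusted p = 2.4e-14, adjusted p = 0.121 with an estimated correlation). They included Arg1, an arginase of alternatively activated macrophages, at 19.5 ± 18.3 CPM in Mem and 2.52 ± 1.34 in Mem+Sol (log2 -2.91 ± 0.46, adjusted p = 0.015, -3.02 and -3.0 in the batches), and the anion exchanger Slc26a4 (-2.38 ± 0.40, -2.03 and -3.21). Cell cycle genes fell in 11 of 15 (15 adjusted over the list alone, median -0.97, camera adjusted p = 5.6e-18, adjusted p = 0.151 with an estimated correlation). Cdk1 was at -1.45 ± 0.25 (-1.54 and -1.38) and Top2a at -1.07 ± 0.20 (-1.05 and -1.17). Goblet cell genes fell in 2 of 12 (6 adjusted over the list alone, camera adjusted p = 6.1e-06, adjusted p = 0.151 with an estimated correlation). Muc5ac was at -1.92 ± 0.33 (-2.37 and -1.89). Antimicrobial genes fell in 4 of 7 (5 adjusted over the list alone, camera adjusted p = 6.4e-06, adjusted p = 0.0633 with an estimated correlation). Lcn2 was at -1.12 ± 0.20 (-1.19 and -1.11). T cell activation genes fell in 3 of 15, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.0e-05, adjusted p = 0.277 with an estimated correlation). Foxp3 and Clca3, chosen here after their values were seen, gave -0.89 (adjusted p = 0.055) and -2.39 (adjusted p = 0.053), short of the threshold. Matrix genes fell in 2 of 16 (10 adjusted over the list alone, camera adjusted p = 2.0e-07, adjusted p = 0.276 with an estimated correlation). Timp1 was at -1.12 ± 0.20 (-0.96 and -1.47). Dendritic cell genes fell in 3 of 12, with 6 lower and 1 higher over the list alone (camera adjusted p = 0.0014, adjusted p = 0.277 with an estimated correlation). Type 2 lymphocyte genes fell in 1 of 10 (4 over the list alone, camera adjusted p = 0.0027, adjusted p = 0.276 with an estimated correlation). Macrophage genes had no called member, 6 lower over the list alone (camera adjusted p = 0.00031, adjusted p = 0.342 with an estimated correlation). B cell and cytotoxic genes had no called member, over all genes or the list alone, and passed upwards (medians 0.46 and 0.40, camera adjusted p = 0.0027 and 0.00043, and adjusted p = 0.479 and 0.452 with an estimated correlation). Airway genes passed upwards too, with 1 of 14 called and 3 over the list alone (camera adjusted p = 0.0085, adjusted p = 0.454 with an estimated correlation). The other 16 lists did not pass (camera adjusted p 0.0711 to 0.889).

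The largest increases in Mem+Sol over Mem lungs were in Csn2 (9.69 ± 0.47, 10.96 and 8.45 in the batches), Tnfsf15, Ankrd63 (1.38 ± 0.28, 0.95 and 1.57), Fank1 (1.26, 1.11 and 1.25), Klhl29 (1.22 ± 0.18, 1.63 and 0.70), Cst8 (1.17, 1.13 and 1.22), the vasoconstrictor endothelin, Edn1 (1.1 ± 0.15, 1.34 and 0.81), and Galnt15 (1.1, 0.77 and 1.25). The largest decreases were in Fbp1 (-4.70 ± 0.88, -5.74 and -3.54), Chil4 (-4.20 ± 0.81, -6.04 and -2.57), Rnase2a (-3.60 ± 0.66, -4.66 and -2.75), Ccl24 (-3.52 ± 0.67, -4.55 and -2.29), Mmp12 (-3.43 ± 0.66, -3.78 and -3.42), Cd163l1 (-3.30 ± 0.37, -3.95 and -2.44), Arg1 and Slc26a4. Of the 41 named genes that were called, 35 were lost without Mem replicate 2 (adjusted p 0.0515 to 0.140), 34 without Mem+Sol replicate 3 (0.0510 to 0.124) and 19 without Mem+Sol replicate 1 (0.0503 to 0.107). The others were 14 without Mem replicate 3 (0.0505 to 0.0820), 12 without Mem replicate 4 (0.0546 to 0.10), 11 without Mem+Sol replicate 4 (0.0510 to 0.0942), 7 without Mem+Sol replicate 2 (0.0519 to 0.0718), 4 without Mem replicate 5 (0.0556 to 0.0730) and 0 without Mem replicate 1. Csn2, Tnfsf15, Cd163l1, Klhl29 and Edn1 were called under each left-out library, and without a sex term 26 of the 41 were lost. In total 137 genes were higher and 218 lower by edgeR's quasi-likelihood test, and DESeq2 called 979. With only the 2 genotypes compared 33 were called (18 higher and 15 lower), with no batch term 34, and with no sex term 143. The count was 30 without Mem replicate 2 (17 higher and 13 lower), 36 without Mem+Sol replicate 3 (21 and 15), and 138 without Mem replicate 3. It was 149 without Mem replicate 4, 144 without Mem+Sol replicate 4, 217 without Mem+Sol replicate 1, 648 without Mem+Sol replicate 2, 21 in batch 1 alone and 1736 in batch 2 alone.

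**Figure D4:**
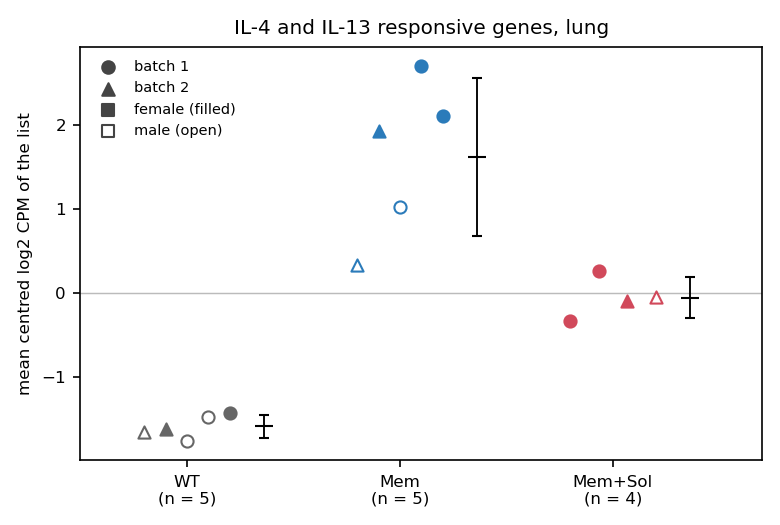
Mean log2 CPM of the 16 IL-4 and IL-13 responsive genes in each lung library by genotype, each gene centred on its mean over the lung libraries, with circles for sequencing batch 1, triangles for batch 2, filled symbols for females and open symbols for males. The group means are -1.58 in WT, 1.62 in Mem and -0.05 in Mem+Sol.

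The casein gene Csn2 and its neighbours Csn3 and Amtn were read in Mem+Sol libraries of both tissues or of the lung. Csn2 lies on chromosome 5 at 87692619 to 87699429 of GRCm38, Csn3 at 87925579 to 87932550, and Amtn, an enamel protein gene, at 88376108 to 88385916. In the lung the Csn2 level was 0.0119 CPM in WT, 0.244 in Mem and 206 ± 137 in Mem+Sol, and Csn3, chosen in the lung after its values were seen, was at 0, 0.0178 and 1.55 ± 0.49 CPM. With 0 counts of Csn3 in WT lungs against 197 in Mem+Sol, Csn3 was at least 77.6-fold higher, taking 3 counts as the most that 0 allows. Amtn, also chosen after its values were seen, stood at 0.0523, 0.0769 and 3.04 ± 1.33 CPM in the lung (6.03 ± 0.59 against WT, adjusted p = 0.00034), and no ileum Mem+Sol library held a count of it. The nearby genes Utp3 (0.18), Rufy3 (-0.01), Grsf1 (0.07) and Ythdc1 (-0.08), looked up after the caseins were seen, passed no test in Mem+Sol lungs against WT (adjusted p 0.287 to 0.952).

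**Figure D5:**
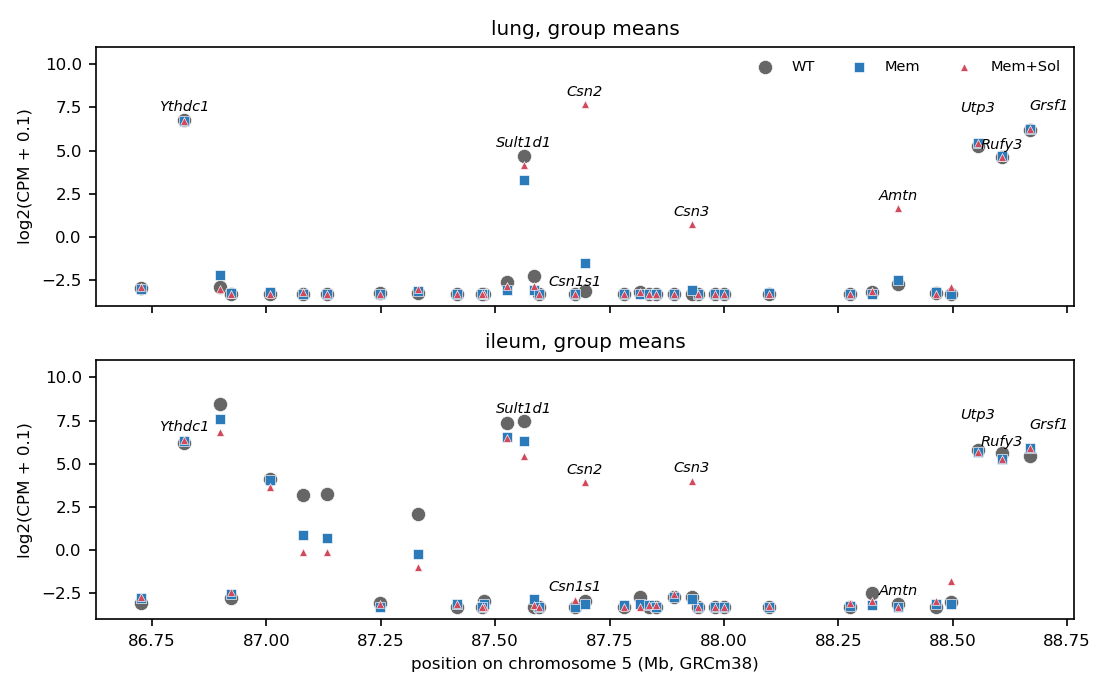
Mean level of each gene within 1 Mb of Csn2 on chromosome 5 (GRCm38) as log2(CPM + 0.1) in lung and ileum, with circles for WT, squares for Mem and triangles for Mem+Sol. In the lung the Mem+Sol means of Csn2 (206 CPM), Amtn (3.04) and Csn3 (1.55) stand above the other genotypes.

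The genotype effects differed between the tissues for 1388 genes in Mem and 3053 in Mem+Sol, of 16867 tested jointly. In Mem, the effect was more positive in the lung for 600 genes and in the ileum for 788. Among the differences towards the lung were Plb1 (8.77, adjusted p = 0.011), Muc5ac (7.62, adjusted p = 0.0056), Clca3 (6.55, adjusted p = 8.6e-06), the ubiquitin-like Ubd (6.40, adjusted p = 0.047) and Ccl20 (6.35, adjusted p = 0.0016). Among those towards the ileum were the defensin Defb1 (-6.55, adjusted p = 0.034), Capn13 (-5.95, adjusted p = 2.7e-05) and Pla2g4c (-5.80, adjusted p = 0.00028). Muc5ac and Ccl20 did not pass the count filter in the ileum, nor Defb1 in the lung, and in the tissue where they were tested their log2 fold changes were 2.93, 4.26 and 4.35. In Mem+Sol, 1104 genes were more positive in the lung and 1949 in the ileum. Ubd (7.99), Plb1 (7.50), Cyp2b10 (6.92), Reg3g (5.76) and Slc5a12 (5.31) were among those towards the lung (adjusted p 0.0012 to 0.015), and Reg4 (-9.62), the lipase Pnliprp2 (-9.39), Tnnt3 (-8.64), Pla2g4c (-7.22) and Olr1 (-6.80) towards the ileum (adjusted p 1.6e-05 to 0.039). Reg4 and Pnliprp2 did not pass the count filter in the lung (4.79 and 3.73 in the ileum), nor Olr1 and Cyp2b10 in the ileum (0.47 and 0.28 in the lung). For the genes filtered out in 1 tissue the size of the difference rests in part on counts that the filter of that tissue left out. Over the 14236 genes that passed the filter in both tissues 1445 differed in Mem and 3005 in Mem+Sol. The Plb1 differences rest on WT ileum replicate 2, without which its ileum decrease was not called (adjusted p = 0.182 in Mem and 0.261 in Mem+Sol). In Mem+Sol, for Slc5a12 and Reg3g the lung minus ileum difference arose with a decrease in the ileum and no called change in the lung. Tissue and sequencing batch coincide, since the ileum libraries were batch 3 and the lung libraries batches 1 and 2, so a batch that changed the genotype effect would enter these differences.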

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

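The tests of milk genes, of the genomic region, of the exchange of WT replicate 4 with Mem+Sol replicate 2 and of the label of ileum Mem replicate 1 were chosen only after the result was seen. In 63 groups of libraries, 10 held 1 library far from the others by Dixon's test, where chance alone picks about 1 in 20, or 3.15. These were Csn2 in ileum WT replicate 5 (0.152 CPM, others 0), ileum Mem replicate 5 (0.0814, others 0), lung Mem replicate 2 (0.712, others 0.109 to 0.151) and lung Mem+Sol replicate 2 (410, others 118 to 155). The others were Csn3 in lung Mem replicate 4 (0.0890, others 0), Retnlb in ileum WT replicate 1 (26.5, others 0.777 to 3.91) and Reg3g (2263, others 70.2 to 115) and Cyp3a11 (3.44, others 0.0594 to 0.284) in ileum Mem replicate 1. So were Gzma in ileum Mem+Sol replicate 5 (31.8, others 2.05 to 9.81) and Retnla in lung WT replicate 5 (69.3, others 37.0 to 46.3). In the 3 groups whose other libraries held 0 any count is flagged, so the rate of 1 in 20 does not apply to them. For the rest that rate holds only for normally distributed values, and the values were not log-transformed. All 10 flagged libraries were the highest of their group, which skewed values would also give. The excess over 3.15 therefore does not by itself mark faulty libraries.

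The effect of the genotype differed between lung and ileum for 1388 genes in Mem and 3053 in Mem+Sol, by a test of the difference itself. For Mem, lung minus ileum, the named genes included Defb1 (-6.55), Capn13 (-5.95), Pla2g4c (-5.80), Plb1 (8.77), Muc5ac (7.62), Clca3 (6.55), Ubd (6.40), Ccl20 (6.35) and Tnfsf15 (1.69). For Mem+Sol they were Reg4 (-9.62), Pnliprp2 (-9.39), Tnnt3 (-8.64), Pla2g4c (-7.22), Olr1 (-6.80), Ubd (7.99), Plb1 (7.50), Cyp2b10 (6.92), Reg3g (5.76), Slc5a12 (5.31) and Tnfsf15 (2.92). Defb1, Reg4 and Pnliprp2 did not pass the count filter in the lung, nor Muc5ac, Ccl20, Olr1 and Cyp2b10 in the ileum, so the size of their differences rests in part on counts that the filter of that tissue left out. Those of Plb1 rest on WT ileum replicate 2 (1343 CPM), without which the ileum decrease was not called (adjusted p = 0.182 in Mem and 0.261 in Mem+Sol).

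Csn2, Csn3 and Amtn were read in Mem+Sol lungs at levels that WT and Mem did not reach. Milk or mammary tissue in the lung samples was argued against, since 5 other milk genes (Csn1s1, Csn1s2a, Wap, Lalba and Glycam1) summed to 0.0608% of the Csn2 counts in Mem+Sol lungs, under a bound of 1%. In Mem+Sol ileum they summed to 23 counts against 2124 of Csn2, or 1.08%, above that bound, so the bound did not decide the question there. Of these genes, Csn1s1 stood at 0.0353 CPM and Csn1s2a at 0 in Mem+Sol ileum, against 15.1 for Csn2. As far as these 2 caseins go, the values argue against milk in the ileum as well. A change in 1 genomic region of the Mem+Sol line was not decided. Of 11 positioned genes that were higher in Mem+Sol lungs than in both other genotypes, 3 lay within 1 Mb of another (permutation p = 0.004 over 100000 draws). These were Csn2, Csn3 and Amtn, the genes that prompted the test, so its p-value restates the observation. Of the other genes between Csn2 and Amtn, the highest in Mem+Sol lungs was Prol1, at 0.0154 CPM. Mem+Sol ileum held reads of Csn2 and Csn3 but none of Amtn. The hypothesis was found and tested on the same data, and the sequence of the transgene and its place of insertion were not analysed here.

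IL-4 and IL-13 responsive genes were lower in Mem+Sol than in Mem lungs, by 1.67 in the mean centred log2 CPM of 16 members (difference -1.67, exact permutation p = 0.0159 over 126 splits, n = 4 and 5). This was 1 of 28 lists tested in the comparison, and the permutation p was not adjusted over them. Sequencing batch was argued against, since the smaller of the within-batch differences was -1.20 against an SD of 0.608. Unequal numbers of males and females were argued against too, since among females the difference was -2.30 against an SD of 0.585. Both SDs pool the 3 genotypes, and the SD of the Mem scores alone was 0.936, against 0.138 in WT. The batch argument is therefore weak: in batch 2 the 2 Mem libraries scored 0.338 and 1.93, and the 2 Mem+Sol libraries -0.0892 and -0.0412. The difference was smaller among the few males, with scores of 0.338 and 1.03 in Mem and -0.0412 in the 1 Mem+Sol male, against at least 1.93 in the Mem females. An exchange of WT replicate 4 with Mem+Sol replicate 2 was argued against by Csn2, at 410 CPM in the library labelled Mem+Sol replicate 2 and 0 in WT replicate 4. The form of TL1A that the genotypes make, its level, and other differences between the lines stay open as untested biological explanations.

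Ileum Mem replicate 1 lay apart from the other Mem libraries, with a tuft cell score of -0.559 against 0.812 to 1.15 in the others and -2.05 to -1.20 in WT (SD 0.320). An exchange with WT replicate 5 was not decided. The score of that library (-1.20) lay below the lowest other Mem library by more than 3 SD, but so did that of Mem replicate 1 itself. The split that exchanged these libraries called 2327 genes, against 1205 with the real labels. A first bound for that test, the range of the other WT libraries (-2.05 to -1.42), was missed by WT replicate 5 and was replaced. A WT sample labelled Mem cannot be told apart from a weakly affected Mem sample, since the score lay above the highest WT library by less than 3 SD, although 9 of 13 tuft genes were above every WT library. The library kept its label.

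Other splits of the same libraries were counted for each comparison. As many genes as the real labels gave were called in 2 of 100 splits for ileum Mem against WT (highest other 2327), 1 of 100 for Mem+Sol against WT (3256), and 1 of 100 for lung Mem against WT (538). They were called in 3 of 100 for lung Mem+Sol against WT (1399), 1 of 100 for lung Mem+Sol against Mem (197), and 1 of 40 for the tissue difference in Mem (80) and in Mem+Sol (207), each count including the real labels. For ileum Mem+Sol against Mem, 5 of 100 splits called at least the 2 genes of the real labels (highest other 100), so chance was not excluded for that count. The split with 2327 calls exchanged WT replicate 5 with Mem replicate 1, and that with 1399 set WT replicates 2, 3 and 5 with Mem+Sol replicate 2 against the other 5 libraries. An exchange of WT replicate 4 with Mem+Sol replicate 2 called 1116. Both 1399 and 1116 exceeded the 134 of the real labels, so the rank of 3 in 100 does not tie that count to genotype.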

How the results depend on the processing

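Thinning of the ileum libraries, all alternatives of the shared counts and the values of single genes within each batch were chosen only after the data were seen, and the cause was not tested for any change below. With DESeq2 the calls were 1926 for ileum Mem against WT, 40 for ileum Mem+Sol against Mem, 634 for lung Mem+Sol against WT, 979 for lung Mem+Sol against Mem, and 1804 shared in the ileum and 312 in the lung. Thinned to the smallest ileum library they were 633 for Mem against WT, 2596 for Mem+Sol against WT and 605 shared. With no batch covariate they were 524, 18 and 34 for lung Mem against WT, Mem+Sol against WT and Mem+Sol against Mem, with 13 shared. In batch 1 only they were 956, 15 and 21 with 13 shared, and in batch 2 only, with no sex covariate, 5, 1190 and 1736 with 4 shared. With no sex covariate lung Mem+Sol gave 243 against WT and 143 against Mem, with 138 shared, with the replicate block 68 against WT and 37 shared, and with only the 2 genotypes compared 33 against Mem. Leaving out 1 library gave 448 to 2396 calls for ileum Mem against WT, 3069 to 4793 for ileum Mem+Sol against WT, and 2 to 8 for ileum Mem+Sol against Mem. In the lung it gave 627 to 2006 for lung Mem against WT, 10 to 500 for lung Mem+Sol against WT, and 30 to 648 for lung Mem+Sol against Mem. The shared counts were 441 to 2156 in the ileum and 7 to 217 in the lung. The lists passing camera fell with an estimated correlation from 15, 16 and 9 to 0, 0 and 0 in the ileum (Mem against WT, Mem+Sol against WT, Mem+Sol against Mem) and from 15, 14 and 12 to 1, 0 and 0 in the lung. With the directional fry test 1 list passed in ileum Mem+Sol against Mem, 8 in lung Mem+Sol against WT and 6 in lung Mem+Sol against Mem, and with mixed fry 1 in ileum Mem+Sol against Mem. Tnfsf15 in ileum Mem against WT turned to 0.054 with the replicate block, 0.256 thinned and 0.0074 without WT replicate 2, the highest of -0.53 to 0.0074 with 1 library left out. In ileum Mem+Sol against WT it turned to -0.028 without WT replicate 1, the lowest of -0.028 to 0.58, and against Mem to -0.099 thinned. Tnfrsf25 in lung Mem+Sol against WT turned to 0.0088 with no sex covariate, 0.052 without WT replicate 2 and 0.016 without Mem+Sol replicate 3, with -0.12 to 0.052 over the left-out libraries. Of the named genes that were called, 32 of 79, 24 of 112 and 0 of 2 in the ileum and 25 of 84, 24 of 29 and 36 of 41 in the lung were lost without at least 1 library. In the same order 6, 15 and 0 and 7, 12 and 4 were lost with the replicate block, and 1, 2 and 0 and 3, 1 and 26 with no sex covariate. None was reversed, and none was lost with DESeq2, which gave no adjusted p for 2 and 3 of them in ileum Mem and Mem+Sol against WT.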

Other observations

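The genes below were chosen after their values were seen. Il22ra2, the soluble inhibitor of IL-22, fell in the ileum from 5.08 ± 2.67 CPM in WT (SD, n = 5) to 0.442 ± 0.156 in Mem (log2 -3.42, adjusted p = 0.00067) and 0.123 ± 0.094 in Mem+Sol (log2 -5.27, adjusted p = 3.1e-05), with no called change in the lung. The cytokine genes Il13 (log2 4.59, adjusted p = 0.046) and Il5 (3.61, adjusted p = 0.034) rose in Mem ileum, and likewise in Mem+Sol (Il13 4.11, adjusted p = 0.040, and Il5 3.39, adjusted p = 0.021). The tuft cell cytokine Il25 rose in Mem+Sol ileum (1.95, adjusted p = 0.0095) and gave 1.73 in Mem (adjusted p = 0.052).

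Cd163l1 fell in the ileum of both genotypes (log2 -2.31, adjusted p = 0.0073 in Mem, and -3.38, adjusted p = 0.00021 in Mem+Sol), while in the lung it was lower in Mem+Sol alone, at 0.772 CPM against 3.99 in WT and 8.61 in Mem. The mitochondrial transhydrogenase gene Nnt was lower in Mem+Sol lungs than in WT (log2 -0.60, adjusted p = 0.0029). The bile acid binding protein gene Fabp6 went from 5451 ± 1090 CPM in WT ileum to 297 ± 332 in Mem+Sol (log2 -4.12, adjusted p = 0.0063).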
